A study of Homo sapiens with 2 samples.

How the data were processed

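The series compares 2 libraries of NPKO-1 cells, 1 with a luciferase shRNA as control and 1 with an NRDE2 shRNA. Both were taken at 72 h of shRNA delivery, and mitotic cells were shaken off before harvest. Per the labels' protocols, total RNA was extracted with TRIzol, ERCC spike-in RNA was added, ribosomal RNA was depleted, and stranded libraries were made with the TruSeq Stranded Total RNA kit. The genome build was hg19, per the submitters' processing notes. The aligner, the counter and the annotation are not given in the sources used here. Whether counting used the strand is not given either, so reads of overlapping genes on opposite strands may be assigned to the wrong gene.

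The authors deposited a table of values per gene and library with a gene type, a symbol and an Ensembl ID. No header of the deposited table names its unit, and the values behave as RPKM: each equals whole reads divided by a gene length and by a library total. FPKM cannot be told apart from RPKM here, since a fragment would be counted in the same way. A library total was found as the number that makes 1 read of the smallest step in genes with 1 annotated exon, where the step is shared by 10 or more genes. It was 3608161 for the control and 3541793 for the NRDE2 shRNA library, a ratio of 1.0187. Of the genes with 1 annotated exon, 886 and 907 with low values were used, and 82.4% and 82.3% of those values came out whole within 0.01 reads. With these totals, all 13593 genes above 0 in both libraries gave ratios of whole numbers, and 0 did so with both totals raised by 1 read. The reads of a gene are then known up to a whole-number factor common to both libraries. For 12412 genes a transcript length in GENCODE v29 is a multiple of the reduced length and settled that factor. Where several fitted, the longest was taken, which can make intervals too narrow. For the other 3795 genes the smallest reads were kept, which makes their intervals too wide rather than too narrow. No count test was run, since each group has 1 library. The table as analysed here holds no ERCC rows, so spike-in scaling was not used.

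Symbols are those of the deposited table. Where it has none (7077 rows) or a date in its place (23 rows), the symbol came from a name table by Ensembl ID. GENCODE v29 (GRCh38) matched 91.9% of IDs and gave exons, introns, GC content of the longest transcript and 3' UTRs. It was matched by ID, and no coordinates were converted between builds.

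Log2 ratios are log2(RPKM + 0.5) in the NRDE2 shRNA library minus that in the control, which understates the change of low genes. Folds are ratios of RPKM without the pseudocount. A gene was expressed at a mean of 1 RPKM or more. Counting intervals of a ratio are exact Clopper-Pearson intervals at 95%, conditional on the reads of both libraries, and those of bin medians come from order statistics. Reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only. What counting error alone gives for the number of 2-fold genes was simulated 100 times from the pooled reads. A list's median was set against 10000 random lists of the same size, drawn from 20 bins of mean expression, as a description of these libraries. A list needed 5 expressed members. Intervals of Spearman's rank correlation come from 200 bootstrap draws over genes.

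The lists and the rule for named genes were fixed before the data were examined. The rule takes NRDE2, then the 12 highest and 12 lowest log2 ratios among genes with a mean of 5 RPKM or more, then the 3 largest absolute log2 ratios of each list. Small structured RNAs with symbols that begin with fixed prefixes, and genes without an HGNC-like name, are left out. The prefixes do not cover RNVU, so the U1 variant RNVU1-18 stays among the named genes. Genes with only an Ensembl ID were treated as without a name. This removed 335 and 366 of 6594 genes, 60 of them above the last of the highest genes and 25 below the last of the lowest. The text and the figure of named genes give only part of the genes the rule takes. Besides these, the abundant structured RNAs were chosen after their values were seen, and the markers of other cells named are those with a mean of 1 RPKM or more.

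The 7-mer fit used 8155 expressed protein-coding genes with 50 or more reads in the libraries together, with log2 ratios limited to -2 and 2. It adjusted for the length and GC content of the 3' UTR, the GC content of the transcript and mean expression. The GC trend was removed by medians in 20 bins of GC content. Standard errors of GC slopes come from bootstrap draws over genes.

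The functions were tested on simulated data. In 12000 simulated genes both library totals came back without error, and reads were exact for every gene above 0 in both libraries whose length was known. With counting error only in 16207 genes and 50 genes changed at each size, the 2-fold rule took 8% of genes changed 1.5-fold, 44% at 2-fold, 90% at 3-fold and 86% at 4-fold, and 4.21% of 10994 unchanged expressed genes. Of 400 random lists of 25 genes among 11187, 25 fell outside the central 95% without a shift, and 381 with a log2 shift of 0.2. A planted 7-mer effect of -0.1 in 8143 genes came back as -0.111 with a standard error of 0.00924.

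Alternatives were centring on the median log2 ratio, pseudocounts of 0.1 and 1, no filter and a minimum of 5 RPKM, thresholds of 1.5-fold and 4-fold, means in place of medians, and lists without shared genes. A minimum of 20 reads, protein-coding genes only, removal of the GC trend and exclusion of genes with certain 3' UTR 7-mers were added after seeing the data. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.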

Results

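Gene expression was measured in NPKO-1 cells, an established human line whose source is given as uterine cervix, after lentiviral delivery of a short hairpin RNA (shRNA) for 72 h. The control library came from cells given an shRNA against luciferase, which human cells lack. The NRDE2 library came from cells given an shRNA against NRDE2, a nuclear protein that binds the RNA exosome helicase MTR4. Mitotic cells were shaken off before harvest, so both libraries describe the cells that stayed attached. Each group had 1 library, so the differences below have no replicate check, and no p-value was computed. The 95% counting intervals cover counting error only and compare these libraries, not the conditions. The deposited values are reads scaled by gene length and library total (RPKM), and the totals recovered from them were 3608161 reads for the control and 3541793 for the NRDE2 shRNA library. Of 25377 genes in the table, 11303 had a mean of 1 RPKM or more and were taken as expressed.

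The targeted gene was lower in the library of its own shRNA. NRDE2 (ENSG00000119720; GRCh38 chromosome 14, 90267856 to 90332137, minus strand) stood at 1.24 RPKM in the control and 0.678 RPKM in the NRDE2 shRNA library. The second value is 54.9% of the first, a log2 ratio of -0.56. The mean of both values, 0.957 RPKM, is below 1 RPKM, so NRDE2 was not counted among the expressed genes. Reads behind these values are known only up to a common whole-number factor, and the smallest pair is 13 and 7 reads. At that depth the counting interval runs from 18.5% to 148% of control, so a lower level was not detectable by counting alone. With 3 times as many reads it would run from 30.7% to 95.6%. Beyond its target, the shRNA was compared with the control for all expressed genes, to ask which transcripts differ between the libraries.

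Over all 11303 expressed genes, about as many were higher as lower in the NRDE2 shRNA library. On the log2(RPKM + 0.5) scale 409 were at least 2-fold higher and 422 at least 2-fold lower, and 58.7% of these were small RNAs, many with few reads. In 100 simulations with counting error as the only source of difference, the highest counts were 277 and 274. Among the 9800 expressed protein-coding genes, a restriction made after seeing the data, more were lower than higher: 78 were at least 2-fold higher and 163 at least 2-fold lower, and the counting interval excluded equality for 62 and 142 of them. Counting error alone gave at most 55 and 49. With 20 or more reads required of any expressed gene, also added after seeing the data, 97 were higher and 147 lower of 10000. The median log2 ratio of expressed genes was -0.05. Whether more protein-coding genes stay lower than higher with that median subtracted or the GC trend removed was not computed.

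The genes furthest above control were led by SFT2D1, a Golgi membrane protein gene, with 5.39 RPKM in the control and 24.1 RPKM in the NRDE2 shRNA library (4.46-fold higher, interval 2.76 to 7.55). SCML2, a Polycomb group gene, had 3.37 and 13.0 RPKM (3.86-fold, 2.82 to 5.36). TSPAN6, a tetraspanin, was 2.82-fold higher (2.12 to 3.80), the GTPase-activating protein gene ARHGAP18 2.84-fold (2.03 to 4.04), and SUB1, which encodes a transcription coactivator, 2.78-fold (2.28 to 3.40). The glucocorticoid-induced gene TSC22D3 was 2.52-fold higher and FAM46A, a noncanonical poly(A) polymerase gene, 2.33-fold (2.01 to 2.71). CHCHD6, a subunit of the mitochondrial inner membrane organising complex, was 2.48-fold higher (1.36 to 4.76). The stress-induced gene NUPR1 had a ratio of 2.55 with an interval of 0.934 to 8.01, from 6 and 15 reads at least. The U1 variant RNVU1-18 (4.18-fold) and CKS1BP3, annotated as a copy of CKS1B (3.26-fold), share sequence with other genes, so their values are uncertain. Of the 12 highest genes, 10 have an annotated 3' UTR, and 8 of those hold the 7-mer GTTTGCT there, a property taken up in the closing section.

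The genes furthest below control were BCL7B, a subunit of BAF chromatin remodelling complexes, and KAT2A, a histone acetyltransferase. BCL7B stood at 18.1 RPKM in the control and 4.57 RPKM in the NRDE2 shRNA library (3.96-fold lower, interval 2.67 to 6.02), and KAT2A at 20.1 and 5.18 RPKM (3.87-fold lower, 2.89 to 5.28). GLO1, which detoxifies methylglyoxal, was 3.26-fold lower (99.6 and 30.6 RPKM, interval 2.79 to 3.81), and RCN2, a reticulocalbin, 3.11-fold lower (2.46 to 3.97). Signalling genes followed: STAT3 was 2.84-fold lower (40.0 and 14.1 RPKM, 2.46 to 3.29), NFKB2, an NF-kB subunit gene, 2.85-fold (2.30 to 3.56), and the EGF receptor ligand gene EPGN 3.03-fold (2.03 to 4.64). Also among the 12 lowest were COMMD5 (3.12-fold lower), LAMB2, a laminin chain gene (3.07-fold), F12, coagulation factor XII (3.04-fold), and ZDHHC12, a palmitoyltransferase gene (2.89-fold). BCL7B, GLO1 and RCN2 hold the 7-mer GTGAGTG in the 3' UTR.

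**Figure D1:**
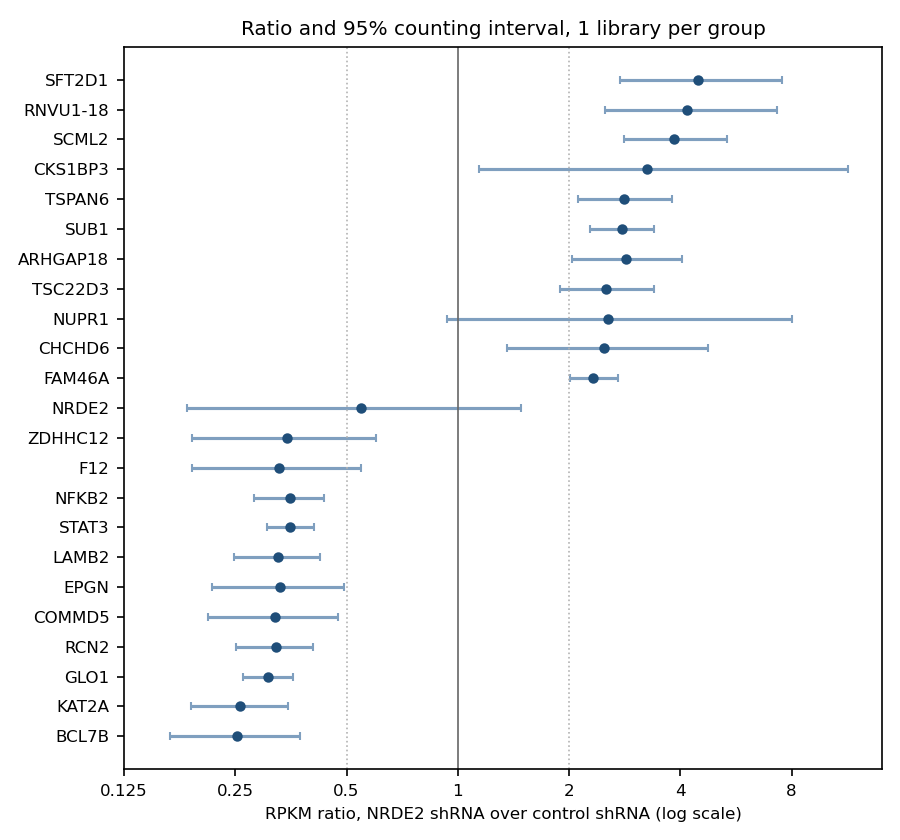
Ratio of RPKM, NRDE2 shRNA over control shRNA (log axis), for NRDE2 and for the genes named here from the 12 highest and 12 lowest with a mean of 5 RPKM or more. Points are the ratios of 1 library per group and bars are exact 95% counting intervals, drawn for NRDE2 at its smallest reads; all but NUPR1 and NRDE2 exclude 1.

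Gene groups fixed before the data were examined were compared with 10000 random lists of the same size and mean expression. Of 34 groups with 5 or more expressed members, 11 had a median log2 ratio outside the central 95% of their random lists. For lists of genes drawn at random, 1.7 would be expected. Genes of a group can vary together between any 2 libraries, and groups share members, so this does not measure an excess over chance. The host genes of small nucleolar RNAs (snoRNAs) had the highest median, 0.35 (100th percentile, 21 genes): 16 were above control, 11 of them with an interval excluding equality, and 1 of the 5 below control. EPB41L4A-AS1 was 1.99-fold higher (1.47 to 2.72), LRRC75A-AS1 1.56-fold, SNHG8 1.54-fold and GAS5 1.49-fold (1.34 to 1.67). The snoRNA genes themselves had a median of 0.295 (347 expressed genes). How reads of a snoRNA within its host were assigned is not given, so the shifts of hosts and snoRNAs cannot be told apart here. Genes of the integrated stress response driven by ATF4 had a median of 0.28 (100th percentile), with 25 of 34 above control. It was 0.13 (percentile 98.48, 25 genes) without genes that hold GTGAGTG or GTTTGCT in the 3' UTR and 0.18 among genes with a mean of 5 RPKM or more. DDIT4, an inhibitor of mTOR signalling, stood at 74.2 and 137 RPKM (1.84-fold higher, 1.64 to 2.07), and NUPR1 is of this list, whereas ATF5 was 2.08-fold lower (1.42 to 3.10).

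Transcripts of cytosolic ribosomal proteins were higher by a small step. Their median log2 ratio was 0.23 (percentile 99.88), 60 of 64 were above control, and the interval excluded equality for 50 of those above and 2 below. The largest ratios were those of RPS25 (1.37-fold, 1.21 to 1.55), RPS27 (1.36-fold, 1.26 to 1.47) and RPS23 (1.36-fold, 1.28 to 1.45). Stress transcripts known to be sensitive to nonsense-mediated decay (NMD) had a median of 0.21 (percentile 98.67), with 12 of 16 above control. This list shares SNHG12 (1.51-fold higher), GAS5 and others with the host genes. SR proteins and hnRNPs, which bind pre-mRNA, had a median of 0.13 (percentile 98.62), with 18 of 26 above control, but the splicing repressor gene PTBP1 stood at 51.5 and 34.4 RPKM (interval 1.33-fold to 1.70-fold lower). With the trend on GC content removed, the medians of the last 2 groups were 0.10 and 0.02 and lay inside the central 95%. Without that correction, the means of their members, 0.17 and 0.0736, also lay inside.

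Proteasome subunit genes were lower nearly throughout. Of 30, 28 were below control, 18 with an interval excluding equality and none above, and the median log2 ratio was -0.23 (percentile 0.07). PSMC4, an ATPase of the regulatory particle, stood at 88.8 and 44.5 RPKM (1.99-fold lower, 1.71 to 2.33), PSMD3 was 1.76-fold lower and PSMD2 1.59-fold lower (1.47 to 1.71). Heat shock protein genes had a median of -0.28 (percentile 1.07), with 16 of 17 below control. HSPA1A was 2.06-fold lower (1.79 to 2.37) and the cochaperone gene BAG3 1.83-fold lower (1.06 to 3.22). HSPA1B, with the same ratio, is nearly identical in sequence to HSPA1A, so the values of both are uncertain. Without genes that hold GTGAGTG or GTTTGCT in the 3' UTR, the heat shock median was -0.21 and lay inside the central 95%.

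The NF-kB inflammatory genes had the lowest median of all groups, -0.51 (percentile 0.20), with 9 of 11 below control. ICAM1, a leukocyte adhesion gene, was 1.96-fold lower (1.65 to 2.34), the NF-kB inhibitor gene TNFAIP3 was also 1.96-fold lower (1.22 to 3.24), and NFKB2 is given above. With the GC trend removed the NF-kB median was -0.33 (percentile 2.08), and the mean of its members, -0.48, lay inside the central 95%. Hypoxia and glycolysis genes had a median of -0.24 (percentile 0.28), with 23 of 31 below control and 17 intervals excluding equality in that direction. The glucose transporter genes SLC2A3 and SLC2A1 were 2.42-fold (2.04 to 2.88) and 1.96-fold (1.65 to 2.34) lower, and ADM was 1.93-fold lower. Reference housekeeping genes had a median of -0.29 (percentile 0.29). ACTB stood at 1074 and 599 RPKM (1.79-fold lower, 1.73 to 1.86) and SDHA was 1.42-fold lower, so these genes do not serve as a constant scale here. Immediate early genes had a median of -0.24 (percentile 2.44), with ETV4 2.06-fold lower (1.51 to 2.84) and NR4A3 1.86-fold higher (1.09 to 3.24). With the GC trend removed the medians were -0.18 for hypoxia and glycolysis, -0.17 for housekeeping and -0.10 for immediate early genes, all inside the central 95%. The housekeeping median was -0.13 among genes with a mean of 5 RPKM or more, and -0.45 without genes in other lists. The immediate early median was 0.00824 with no filter, and without genes that hold either 7-mer it was -0.37, and that of housekeeping genes -0.47.

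**Figure D2:**
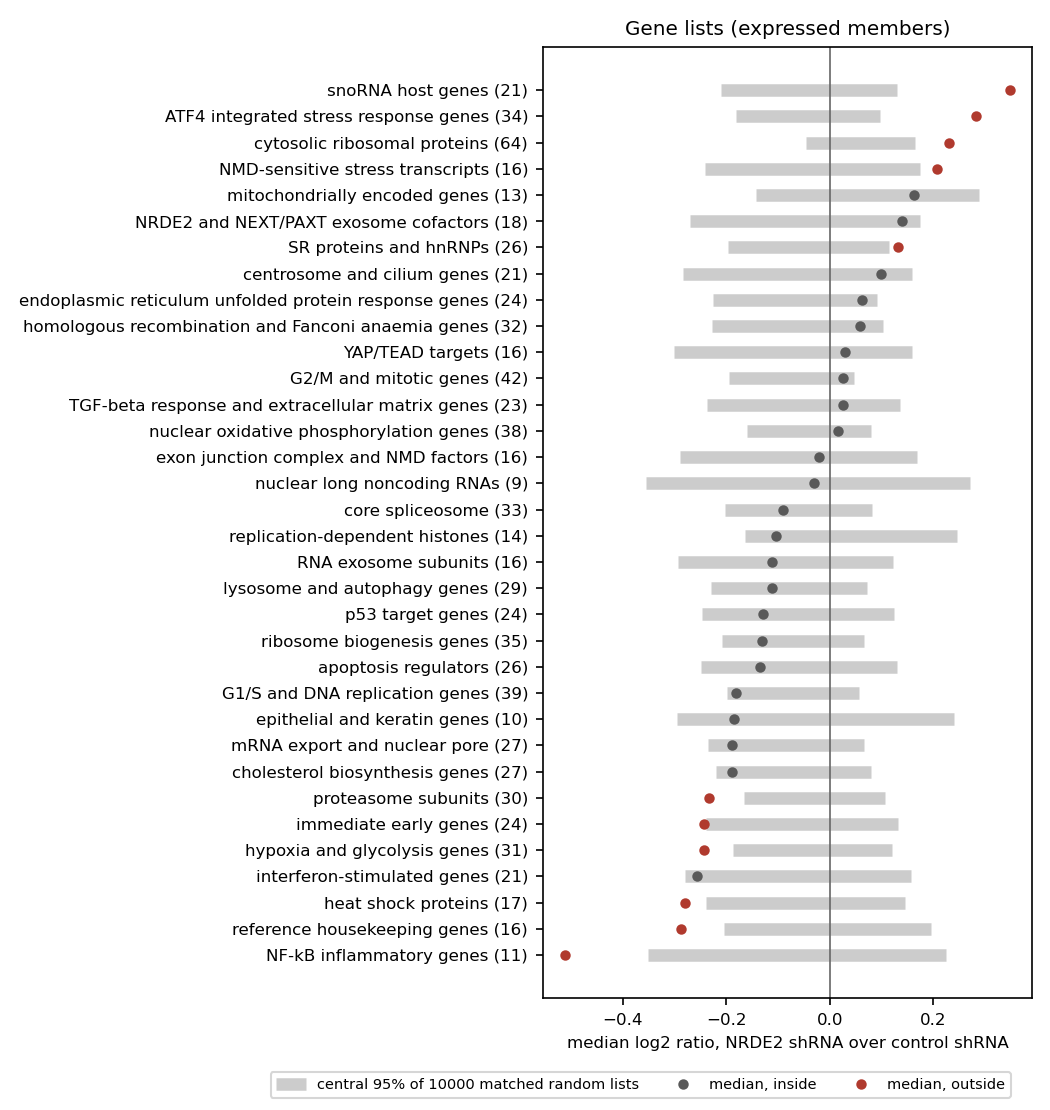
Median log2 ratio (NRDE2 shRNA over control shRNA) of each gene group, with the number of expressed members in parentheses. Grey bars span the central 95% of 10000 matched random lists, and red points mark the 11 medians outside their bar, from -0.51 for NF-kB inflammatory genes to 0.35 for snoRNA host genes.

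The other 23 groups lay inside the central 95%, including those closest to the known partners of NRDE2. The listed cofactors of the nuclear exosome had a median of 0.14 (percentile 95.18, 18 genes). NRDE2 is of this list but fell below the filter. With no filter the median was 0.117 over 19 genes, NRDE2 included. RBM27, which holds GTTTGCT in its 3' UTR, was 2.73-fold higher (1.70 to 4.51) and ZCCHC8 1.68-fold higher (1.14 to 2.52). The median was -0.11 for RNA exosome subunits, -0.02 for exon junction complex and NMD factors, -0.09 for the core spliceosome and -0.19 for mRNA export and nuclear pore genes. Within that last group TPR was 1.95-fold higher (1.42 to 2.71) and NUP85 1.67-fold lower (1.41 to 1.99). Nuclear long noncoding RNAs went both ways around a median of -0.03: NEAT1, the scaffold of paraspeckles, stood at 7.88 and 16.9 RPKM (2.15-fold higher, 1.95 to 2.36), MALAT1 was 1.40-fold higher (1.36 to 1.44) and OIP5-AS1 2.06-fold lower (1.63 to 2.62).

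Cell cycle and genome maintenance genes showed no median outside the central 95%. G2/M and mitotic genes had a median of 0.03 (percentile 94.66), with CENPF 1.99-fold higher (1.46 to 2.73), ASPM 1.93-fold higher and the mitotic kinase gene AURKA 1.64-fold lower (1.46 to 1.86). G1/S and DNA replication genes had a median of -0.18 (percentile 4.88): 28 of 39 were below control, among them CDC45, a replicative helicase subunit, at 22.3 and 10.1 RPKM (interval 1.67-fold to 2.93-fold lower), while CCND1 was 1.84-fold higher (1.59 to 2.13). Centrosome and cilium genes had a median of 0.10, with CEP57 2.06-fold higher (1.58 to 2.71) and TUBG1 2.01-fold lower (1.69 to 2.38). The medians were -0.10 for replication-dependent histones, 0.06 for homologous recombination and Fanconi anaemia genes, -0.13 for p53 target genes and -0.14 for apoptosis regulators. RAD51AP1 was 1.87-fold higher (1.41 to 2.49) and H2AFX 1.82-fold lower (1.49 to 2.22).

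Interferon-stimulated genes had a median of -0.26 (percentile 3.80), with IRF9 2.72-fold lower (1.41 to 5.59). Cholesterol biosynthesis genes had a median of -0.19 (percentile 5.22), with MSMO1 1.92-fold lower (1.62 to 2.30). The unfolded protein response of the endoplasmic reticulum had a median of 0.06 (percentile 95.01), with HSP90B1 1.43-fold higher and DERL1 1.62-fold lower. Medians were 0.16 for mitochondrially encoded genes, 0.01 for nuclear oxidative phosphorylation genes, -0.13 for ribosome biogenesis genes and -0.11 for lysosome and autophagy genes. They were 0.03 for YAP/TEAD targets, 0.03 for the TGF-beta response and extracellular matrix, and -0.19 for epithelial and keratin genes.

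Abundant structured RNAs took different shares of the libraries. The U1 gene RNVU1-7 held 7.28% of control reads and 10.9% of reads in the NRDE2 shRNA library (interval 1.49-fold to 1.51-fold higher). The U2 gene RNU2-2P was 1.47-fold higher, the U4 genes RNU4-1 and RNU4-2 were 1.47-fold (1.42 to 1.52) and 1.43-fold higher, and RN7SK, which holds the elongation factor P-TEFb inactive, was 1.19-fold higher. RNA5S12, a 5S ribosomal RNA gene, held 2.86% of control reads and 0.968% in the NRDE2 shRNA library, 2.95-fold lower (2.92 to 2.99). These RNAs have many near-identical gene copies and ribosomal RNA was depleted before sequencing, so their values are uncertain. Protein-coding genes took 58.1% and 55.9% of reads.

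The log2 ratio varied with base composition. Across 10732 expressed genes with an annotated transcript, Spearman's rank correlation between the log2 ratio and the GC content was -0.274 (bootstrap interval over genes -0.292 to -0.254). The median log2 ratio was 0.07 in the lowest of 5 equal bins of GC content and -0.24 in the highest. The rank correlation was 0.169 for the median intron length (9687 genes), 0.024 for gene length and -0.004 for the number of exons. Genes in the lowest bin of intron length, up to 582 nt, had a median log2 ratio of -0.19, against 0.00 in the highest bin. For gene length, the rank correlation was -0.050 among genes with a mean of 5 RPKM or more, the opposite sign. Gene length was recovered from the deposited values, and where the common factor of reads is not settled it can be a fraction of the true length. The shortest is 7 nt, so the relation with gene length is uncertain. These 4 relations are across genes, which are not independent replicates.

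**Figure D3:**
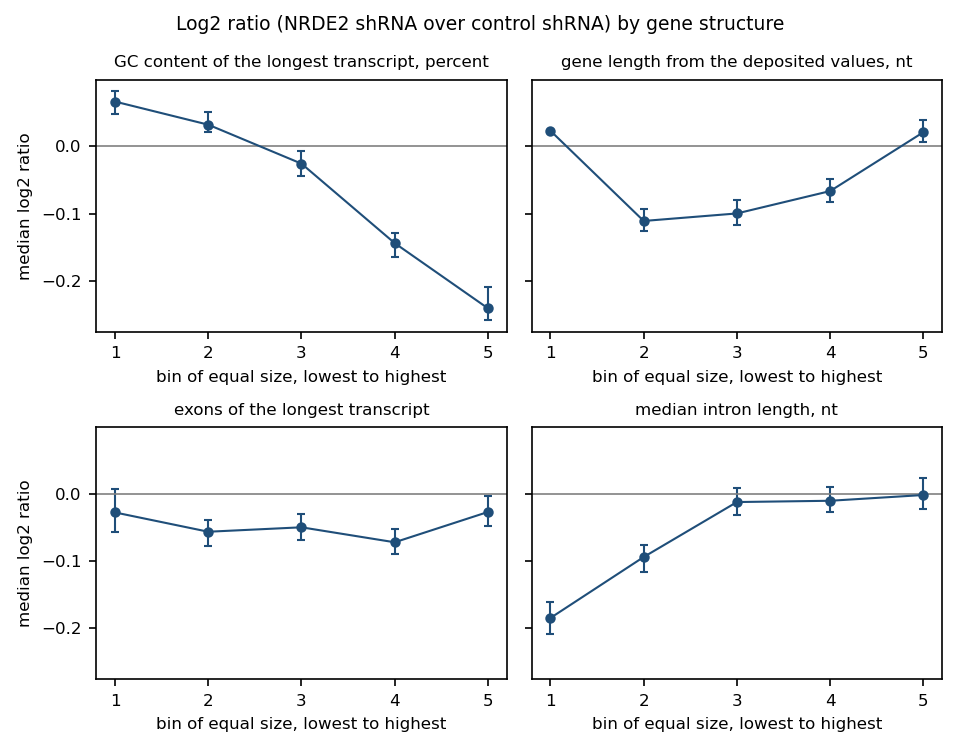
Median log2 ratio (NRDE2 shRNA over control shRNA) in 5 bins of equal size for GC content, gene length, exon number and median intron length, with exact 95% intervals of the median over genes. Gene length is as recovered from the deposited values and can be too short where the common factor of reads is not settled. The median runs from 0.07 to -0.24 over the GC bins and from -0.19 to 0.00 over the intron bins.

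Markers of other cell types were low, against a floor at which 3 reads in a gene of 3000 nt correspond to 0.277 and 0.282 RPKM. All 9 fibroblast markers in the table and all 5 markers of kidney packaging or neural cells had a mean under 1 RPKM, as did 5 of 6 endothelial and 6 of 8 blood markers. The exceptions were ERG, CD68 and HBA1. ERG stood at 0.936 and 1.46 RPKM, CD68 at 3.55 and 3.61 RPKM, and HBA1 at 7.69 and 10.3 RPKM. The lists held 10 fibroblast, 10 kidney packaging or neural, 8 endothelial and 12 blood markers. Those absent from the table, PAX2 and LHX1 among them, could not be assessed.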

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

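The minimum of 20 reads, the restrictions to protein-coding genes or random lists of them, the GC correction and the exclusion of 7-mer genes were chosen after seeing the data. No paired analysis was possible because each group has 1 library, and leaving out a library was not possible. Scaling to ERCC spike-ins was not run, as the table used here has no such rows.

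The number of genes at least 2-fold apart (831, 409 higher and 422 lower) depends on which genes are admitted. It was 1526 (766 higher, 760 lower) with no filter, 227 (110 and 117) at a mean of 5 RPKM, 244 (97 and 147) with 20 or more reads, and 241 (78 and 163) among protein-coding genes, where lower genes outnumber higher ones. It was 2253 (933 and 1320) at 1.5-fold and 417 (218 and 199) at 4-fold. Fewer or more genes admitted, or another threshold, change the total by construction, but do not fix the share of higher genes in it. Centring, which subtracts -0.047, both pseudocounts, the GC correction and the exclusion of 7-mer genes kept the counts within 1.5 times. Over all expressed genes, higher ones outnumbered lower ones after centring (440 and 384) and after the GC correction (318 and 286). The balance among protein-coding genes was not computed under either. Of calls, 32.4% were higher among protein-coding genes and 49.2% among all.

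The medians of 4 lists stayed outside the central 95% of random lists under all 10 alternatives: snoRNA host genes (0.29 to 0.39), ATF4 genes (0.13, without 7-mer genes, to 0.33), cytosolic ribosomal proteins (0.21 to 0.28) and proteasome subunits (-0.30 to -0.19). Other lists moved across the limit, and the cause was not tested. With the GC trend removed, NMD-sensitive transcripts (0.10), SR proteins and hnRNPs (0.0224), immediate early (-0.10), hypoxia and glycolysis (-0.18) and housekeeping genes (-0.17) came inside, and interferon-stimulated genes (-0.27) went outside. With means, NMD-sensitive transcripts (0.17), SR proteins and hnRNPs (0.0736), NF-kB (-0.48), immediate early (-0.16) and housekeeping genes (-0.24) came inside, and histones (-0.20) went outside. Without a filter, immediate early genes reversed to 0.00824, and centrosome (0.17) and interferon-stimulated genes (-0.29) went outside. At 5 RPKM the housekeeping median was -0.13, and with a pseudocount of 0.1 the immediate early median was -0.25, both inside. SR proteins and hnRNPs came inside without shared genes (0.13). Without 7-mer genes they stood at 0.12 and heat shock proteins at -0.21, both inside, while homologous recombination (0.17) and unfolded protein response genes (0.14) went outside. NMD-sensitive transcripts kept only 2 members without shared genes, so no value was computed.

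The rank correlation with GC content was -0.313 at a mean of 5 RPKM. The rank correlation with recovered gene length was 0.058 without small structured RNAs and reversed to -0.050 at 5 RPKM, and that with exon number was 0.027 and -0.066. The NRDE2 log2 ratio stayed within its counting interval under centring and both pseudocounts. Depth limits low genes most: for NRDE2, 13 and 7 reads do not by themselves exclude equality.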

Other observations

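The patterns weighed below, the 7-mers, the GC trend and 4 of the gene lists, were picked after the data had been seen. What each result would mean was written before its test was run, except for the permutation test and the reorderings of GTTTGCT, where it was written after.

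Among mitochondrially encoded genes MT-ND3 was 1.41-fold higher in the NRDE2 shRNA library (1.29 to 1.56), MT-ATP8 1.40-fold (1.29 to 1.51) and MT-CYB 1.24-fold (1.18 to 1.30), while 3 of 13 such genes were lower with an interval excluding equality. snoRNA genes with a mean of 1 RPKM or more had a median log2 ratio of 0.29, with 75 of 347 at least 2-fold higher and 36 at least 2-fold lower, at a median of 18 reads in the libraries together. In sense-intronic transcripts, which lie within introns of other genes, the median was 0.27 over 54 genes, with 13 at least 2-fold higher and 3 lower, at a median of 7.5 reads. The cell line's epithelial genes were also uneven, with KRT80 1.82-fold lower (1.41 to 2.36), PKP3 1.79-fold lower (1.11 to 2.94) and the desmoplakin gene DSP 1.53-fold higher (1.17 to 2.01).

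Short sequences in 3' UTRs went with the log2 ratio. Among 8155 protein-coding genes, GTGAGTG had the lowest z of 16199 7-mers (-8.44; 1077 genes, effect -0.10) and GTTTGCT the highest (9.85; 1500 genes, effect 0.11). Unlike these effects, the medians and shares that follow are not adjusted for the length or GC content of the 3' UTR. They therefore do not separate the number of sites from length or base composition. The median log2 ratio was -0.05 without GTGAGTG, -0.11 with 1 site and -0.14 with 2 or more, and -0.09, 0.05 and 0.14 for GTTTGCT. Of the 96 genes at least 2-fold lower, 24.0% hold GTGAGTG, against 13.2% of all, and of the 35 at least 2-fold higher, 51.4% hold GTTTGCT, against 18.4%.

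A candidate explanation is that the hairpins act through their seeds on transcripts other than their targets, at GTGAGTG for the NRDE2 hairpin and, by the sign, at GTTTGCT for the luciferase hairpin. For GTGAGTG, the effect in 3' UTRs lay below that in coding sequence (difference -0.0783, standard error 0.0216), but it was picked by its 3' UTR effect, so this does not tell for or against pairing. GTAAGTG, which a 5' splice site would also allow, had an effect of -0.0111 (standard error 0.014), while GTTTGCT had an effect in coding sequence too (0.05, standard error 0.0163) and was given no splice-site test. The largest absolute z in 100 permutations, 4.74, argues against chance for both. Reorderings of the letters of 7-mers picked as the most extreme had to be less extreme. For GTGAGTG, the 94 reorderings sharing no 5 letters in a row with it ran from z -3.38 to 1.93. The reverse complements, of equal GC content and not so picked, had effects of 0.0069 (CACTCAC, standard error 0.0132) and 0.0165 (AGCAAAC, 0.0124). The values of the reverse complements argue against GC content as the whole cause for both, in a fit that already adjusts for it. Base composition stays open for both. For GTGAGTG the reorderings cannot decide, since they had to be less extreme. For GTTTGCT the highest reordering (TGTTTGC, z 5.40) also shares GTTTGC with it. As such a seed would need, 4 of 10 annotated NRDE2 transcripts hold GTGAGTG. In the isoform with the longest 3' UTR it lies in the coding sequence, not in the 3' UTR. That 3' UTR holds 1 site of GTTTGCT, the 7-mer set above beside the luciferase hairpin, as do 18.4% of fitted genes in theirs. Of the fitted genes, 6.38% hold GTGAGTG in the coding sequence and 18.7% there or in the 3' UTR. Of the 198 within 25% of that isoform's 13972 nt of coding sequence and 3' UTR, 50% do. Shorter NRDE2 transcripts, of 1384 to 3434 nt, hold it too. As the shares depend on the comparison, the site is weak evidence, and the hairpin sequences are not given in the sources used here. Whether the ratios of BCL7B, GLO1 and RCN2 among the 12 lowest genes reflect the loss of NRDE2 stays open. The same holds for the 8 of 10 highest genes with a 3' UTR that hold GTTTGCT. It also holds for genes named from the lists, among them RBM27, CCND1 and CEP57 with GTTTGCT, and AURKA and MSMO1 with GTGAGTG. NUP85 holds GTTTGCT too but was lower.

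The fall of the log2 ratio with GC content may be a bias between the libraries. Genes with 1 exon, which are not spliced, had a slope of -0.113 per 10 percentage points of GC (standard error 0.0398, 155 genes), and spliced genes -0.134 (standard error 0.00492, 9289 genes). The difference of 0.0206 (standard error 0.0401) argues against an effect on spliced genes with short introns alone. With GC content in the fit, a median intron 10 times as long still went with a log2 ratio higher by 0.0564 (standard error 0.00918), so an added effect of NRDE2 on splicing stays open.

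The shifts of gene groups were set against that trend. With it removed, the median was 0.219 for cytosolic ribosomal proteins, 0.27 for ATF4 genes, -0.303 for proteasome subunits and -0.321 for heat shock proteins. Each was still outside the central 95% of random lists, which argues against the trend with GC content as the whole cause. Ribosomal protein transcripts are short. Random protein-coding genes matched on expression and recovered gene length reached at most 0.0647 at the upper limit of the central 95%, against 0.23 for 63 of these transcripts. Recovered length can differ from that of the expressed transcript (3437 nt for RPS23), so short transcripts as a cause stay open. A response to NRDE2 loss, a response to either hairpin and a difference in culture between 2 dishes all stay open, since each group has 1 library and no second hairpin was analysed here.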
